A study of Mus musculus with 6 samples.

How the data were processed

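Gene expression was measured in mouse embryoid bodies, the rounded aggregates that embryonic stem cells form in suspension and in which they differentiate. Per the labels, cells of the D3 embryonic stem cell line formed bodies that held gelatin-coated microspheres, and the bodies were sampled at 10 days. The microspheres of the 3 control samples carried a red cell-tracking dye, and those of the 3 other samples carried retinoic acid (RA), a vitamin A derivative that acts through nuclear receptors. Total RNA was labelled with biotin as cRNA and hybridized to an Affymetrix mouse expression array, 1 array for each sample, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels describe triplicates without saying that these were separate cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical.

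The deposited values are a linear intensity for each probe set, on 6 arrays and 45101 probe sets, and per the labels they came from the Affymetrix GCOS software with default settings. Its version and the parameters of its signal algorithm are not given in the sources used here. No detection calls were used here. The trimmed mean of the signal, over the values left after taking off 2% at each end, ranged from 108 to 191 between arrays, so the arrays had not been scaled to a common level. The plan written before the data were examined had assumed scaled values. Because they were not scaled, and before any test was run, the main setting became quantile normalization of log2(intensity + 16) between arrays with limma, and the planned fit without scaling became an alternative. All other main choices, the 26 gene lists and the rule for naming genes were made before the data were examined.

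The pseudocount of 16 understates the fold change of dim genes. The 64 control probe sets of the array were left out. Gene names came from the array's annotation table, in which 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. Through the gene identifier, 34741 of the named probe sets matched a gene of the GRCm38.p6 RefSeq table, and 0 symbols needed an update. That table was also used for the chromosome and the order of genes, and no coordinates are given because the array annotation names no genome build. Probe sets whose mean over the 6 arrays lay above the 40th percentile, a log2 level of 5.74, were kept, which left 27022. Each gene was represented by its brightest kept probe set with a single symbol, which gave 13608 genes out of 18194. A group mean below 5.74 is open to background, and it occurred for 27 of the 149 named genes. Of 2102 changed genes with several kept probe sets, 36 had a probe set that changed in the opposite direction. Probe sets of globin, serpin and homeobox family members may also read close relatives.

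The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on the mean value, two-sided, no covariates). P-values were adjusted over genes by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are RA minus control on the log2 scale, with the standard error (SE) of the fit, and group values are means ± SD with n = 3. Gene lists were tested with camera of limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 26 lists. The same test was run with a correlation estimated for each list. The number of members past the threshold when adjusted over the list alone was counted as well. Of 466 different genes in the lists, 386 were measured, and the others, among them T (brachyury) and Gsc, are not analysed here. Array quality was read from the ratio of 3-prime to 5-prime probe sets for Gapdh and actin, with an exact two-sided permutation test whose smallest possible p is 0.1 with 3 against 3 arrays.

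Genes were named by a fixed rule. The rule took the 12 largest rises and 12 largest falls past the threshold whose arrays did not overlap between groups, leaving out predicted and clone-named genes. It took up to 4 members with the smallest p from each list, with at most 3 of one direction where both directions held a changed member. It also took all changed members of the lists for retinoic acid response, epiblast, primitive streak and visceral endoderm, plus Pou5f1, T, Fgf5 and Afp. Genes named outside this rule are said to be so where they appear.

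The procedure was tested on simulated data made from the 6 arrays with 13639 genes. It recovered 61% of genes changed by 1 and 84% of genes changed by 2 on the log2 scale, and 5.49% of its calls were unchanged genes. Only 100 genes were changed by each of these sizes, against 4076 genes called in the data. The simulated noise was independent between genes, and no array with low 5-prime signal was simulated. These rates therefore need not hold for the real comparison. Alternatives covered the scaling, pseudocount, signal filter, choice of probe set, variance model, fold minimum, replicate number as a block, and each array left out in turn. For lists they covered the estimated correlation and the fry test. Scaling to a common trimmed mean, leaving out 2 arrays in doubt together, and leaving out chromosome 11 were added after seeing the data. A further 13 lists were also chosen after the main results were seen. Plots were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.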

Results

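The data are 6 arrays of embryoid bodies at day 10, 3 from bodies with control microspheres and 3 from bodies with RA microspheres. The title of the study refers to an early streak phenotype, and the comparison asks which genes differ when RA is delivered from within the bodies. The median deposited signal was 54.7, 63.6 and 41.4 on control arrays 1, 2 and 3, and 61.7, 63.7 and 65.5 on the RA arrays. After normalization, log2 values correlated at 0.959 to 0.971 across genes within a group and at 0.879 to 0.901 between groups. The first principal component held 64.2% of the variance and separated the groups. The Gapdh 3-prime to 5-prime ratio, a sign of RNA integrity, was 34.0 on RA array 1 and between 3.06 and 4.74 on the other 5 arrays. The actin ratio was 3.69 ± 0.487 in controls and 5.55 ± 1.64 with RA (SD, n = 3, exact permutation p = 0.1, the smallest possible), and all 3 RA arrays lay above the controls.

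Bodies with RA microspheres had higher levels of epiblast genes and far lower levels of heart muscle genes and embryonic globins. With an estimated correlation the epiblast list passed narrowly (limma camera adjusted p = 0.0380) and the heart muscle list did not (limma camera adjusted p = 0.0505). Among the 12 largest rises were Dnmt3b, a de novo DNA methyltransferase, which was 14.8 times higher with RA, and Fgf5, a growth factor of the epiblast, at 14.1 times. The transcription factor genes Pou3f1 and Sox1 were 13.4 and 10.3 times higher, and Fabp7, a fatty acid binding protein of neural progenitors, 11.4 times. The embryonic globin Hbb-y showed the largest fall, 88.9 times lower with RA, from 13.19 ± 0.12 to 6.71 ± 0.20 on the log2 scale (SD, n = 3). Actc1 and Myh6, which encode cardiac actin and myosin, were 69.2 and 48.2 times lower, and Alb (albumin) was 32.9 times lower. The control mean of Sox1 and the RA mean of Myh6 lay below the filter level of 5.74, so these folds are open to background. The control means of Fgf5 and Pou3f1 (5.85 and 5.84) and the RA means of Actc1 and Alb (5.83 and 5.82) lay just above this level.

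The remaining largest rises were Srgn (log2 fold change 4.09 ± 0.27, SE), Pim2 (4.03 ± 0.14), Eras (3.77 ± 0.21), Car4 (3.26 ± 0.08), Cubn (3.22 ± 0.22), Fgf15 (3.21 ± 0.23) and Trh (3.17 ± 0.16). The remaining largest falls were the fibrinogen gene Fgb (-5.12 ± 0.15), the troponin genes Tnnt2 (-5.10 ± 0.20) and Tnni1 (-4.40 ± 0.25), and Myl7 (-5.05 ± 0.14). They also included the platelet chemokine Pf4 (-4.89 ± 0.16), the globin Hba-x (-4.86 ± 0.15), Shisa3 (-4.72 ± 0.20) and the serpin Serpina1b (-4.44 ± 0.20). The control mean of Fgf15 and the RA means of Fgb, Tnnt2, Tnni1, Shisa3 and Serpina1b lay below the filter level. The control mean of Srgn (5.87) and the RA mean of Pf4 (5.88) lay just above it. The limma adjusted p of these 24 genes was at most 1.01e-05. Of 13608 genes tested with limma, 4076 passed the threshold after Benjamini-Hochberg adjustment, 1949 higher and 2127 lower with RA. A change of at least 2-fold was reached by 414 higher and 671 lower genes, and one of at least 8-fold by 14 and 43. In 5987 genes (44.0%) the arrays of the groups did not overlap, where chance gives 10%. Without scaling, 1750 genes were higher and 651 lower, so that 72.9% of calls were higher against 47.8% with quantile normalization, and the median of all genes moved from 0.01 to 0.26. Without RA array 1 and control array 3 together, 1665 genes were higher and 1834 lower.

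Genes of retinoic acid metabolism and response moved in both directions. Cyp26a1, the enzyme that clears retinoic acid, was 8.13 times higher with RA, and the binding proteins Crabp1 and Crabp2 were 2.02 and 1.71 times higher. Rarb, the receptor gene that retinoic acid commonly induces, was 6.81 times lower with RA, Stra8 was 4.42 times lower, and the homeobox genes Meis2 and Meis1 were 4.76 and 3.36 times lower. Aldh1a2 and Rdh10, enzymes of retinoic acid synthesis, were 2.90 and 1.98 times lower, Dhrs3 was 2.10 times lower and Tgm2 2.99 times lower. Of 15 measured members 3 rose and 8 fell, and 4 rose and 8 fell when adjusted over the list alone. The limma adjusted p of these 11 genes ran from 3.84e-08 to 0.00380. The list had a median log2 fold change of -0.99 and a camera adjusted p of 0.00903 in limma, with adjusted p = 0.0703 with an estimated correlation. The means of Rarb and Stra8 with RA lay below the filter level, and Rdh10 did not pass without scaling. Meis1 lies on chromosome 11, whose genes were lower with RA as a whole.

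Epiblast genes rose together. The transcription factor genes Otx2, Zic5, Zic2 and Foxd3 were 5.30, 5.23, 4.01 and 4.86 times higher with RA, the amino acid transporter Slc7a3 6.94 times, and E-cadherin (Cdh1) 2.96 times. Tdgf1, a Nodal co-receptor, was 2.80 times higher. Foxd3 is also in the neural crest list, Tdgf1 in the general pluripotency list and Cdh1 in the epithelium list. Each array measured whole bodies, in which neural genes rose as well, so the cells behind a rise are not known. Smaller rises were found for Sox3 (log2 fold change 1.05 ± 0.32) and Nodal (0.35 ± 0.11), and Epha4 fell (-0.80 ± 0.12). The brightest probe set of Dnmt3a fell (-1.21 ± 0.12), and of its 5 probe sets 3 passed as lower and 0 as higher. They ranged from -1.21 to 0.04, so its call rests on which of them was taken. Of 17 measured members 13 rose and 2 fell, with the same counts when adjusted over the list alone, and the median was 2.00 (limma camera adjusted p = 4.69e-07). With an estimated correlation the camera adjusted p was 0.0380. The limma adjusted p of the called members ran from 3.19e-09 to 0.0308. The call of Dnmt3a was lost without any single control array (-0.0018, -0.09 and 0.21 without control arrays 1, 2 and 3). Its main probe set lay at 9.10, 9.18 and 9.30 on control arrays 1, 2 and 3, with an RA mean of 7.98. These losses therefore go with a switch to another probe set. The call of Sox3 was lost without control array 3 or RA array 2 or 3 (0.74 to 0.96). That of Nodal was lost without any single array except control array 3 (0.31 to 0.37). The control means of Zic2 and Foxd3 lay below the filter level. Without scaling, Nodal and Epha4 did not pass, and 1 member was lower.

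Among general pluripotency genes, Pou5f1 (Oct4) was 5.38 times higher with RA, Lin28a 7.31 times and Sall4 3.56 times, while Dppa2 was 1.56 times lower. Of 12 measured members 8 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone. The median was 1.21, with limma camera adjusted p = 2.34e-06 and adjusted p = 0.0505 with an estimated correlation. Genes of the naive state, which precedes the epiblast, went both ways: Nanog was 1.61 times higher, and Dppa5a, Klf2 and Nr0b1 were 2.28, 2.25 and 2.70 times lower. Of 17 naive members 3 rose and 5 fell, and 3 and 6 did so when adjusted over the list alone. The median was -0.12 and the limma camera adjusted p was 0.382. Without scaling, and without control array 1 or 2 or RA array 3, 3 naive genes were lower. The call of Dppa2 was lost without scaling and without control array 1 or 2 or RA array 2 or 3 (-0.64 to -0.52).

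Measured genes of the primitive streak, the site where mesoderm and endoderm form, were higher with RA as a list, although 9 of 17 did not pass. T had no probe set named for it alone, and Gsc, Wnt3, Fgf8, Tbx6 and Nog lay below the signal filter. Eomes, a T-box factor, rose from 6.80 ± 0.19 to 9.50 ± 0.16 on the log2 scale (SD, n = 3), which is 6.48 times higher. Lhx1 and Foxa2, both transcription factors of the anterior streak, were 6.33 times higher, and Mixl1 was 4.15 times higher. Eomes is also in the trophoblast list and Foxa2 in the visceral endoderm list, so their rises need not come from the streak. Sp5 was 3.23 times higher, Chrd, a BMP antagonist, 2.52 times, Mesp1 2.43 times and Evx1 2.34 times. Of 17 measured members 8 rose and 0 fell, with the same counts when adjusted over the list alone, and the median was 0.63 (limma camera adjusted p = 7.16e-05). With an estimated correlation the camera adjusted p was 0.0470. The limma adjusted p of the called members ran from 1.66e-07 to 0.0105. The control means of Sp5 and Chrd lay below the filter level, and Lhx1 lies on chromosome 11, whose genes were lower as a group. The definitive endoderm and gut list had 7 of 13 members higher and 0 lower, also when adjusted over the list alone. It shares Foxa2, Cdx2 and the unmeasured Gsc with the streak list, and Sox17 and Foxa2 with the visceral endoderm list. Its leading genes were Trh, Sox17 (4.33 times higher), Foxa2 and the chemokine receptor Cxcr4 (3.60 times), and its median was 0.73 (limma camera adjusted p = 0.000361).

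**Figure D1:**
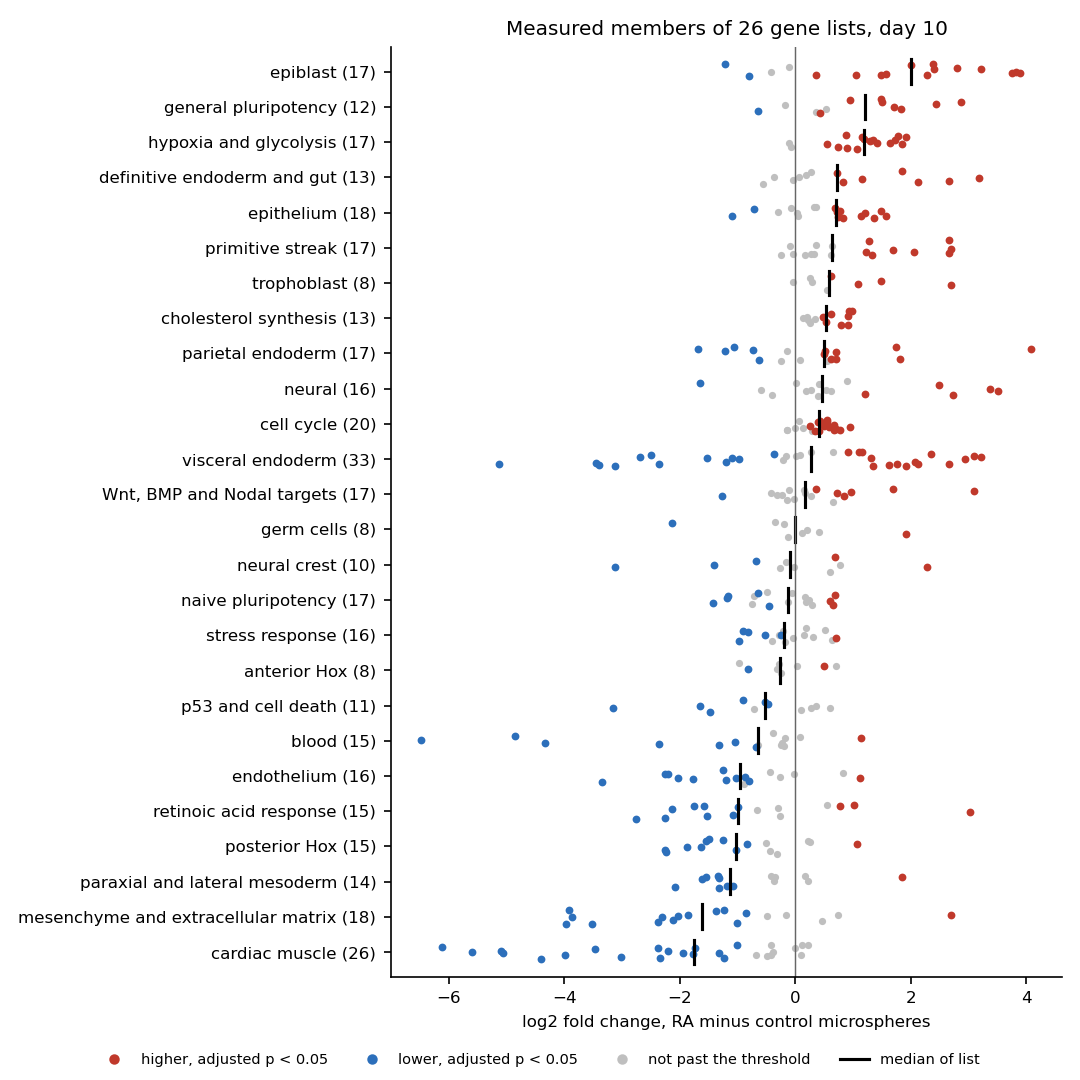
Log2 fold change (RA minus control microspheres, 3 arrays each) of each measured member of the 26 gene lists, with the number of measured members after each name. Each point is a gene, red and blue points passed the limma threshold, and the black bar is the median of the list. Medians run from -1.75 for cardiac muscle to 2.00 for epiblast.

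Visceral endoderm genes moved in both directions. Cubn and Amn, which form an uptake receptor, were 9.29 and 7.65 times higher with RA, and the endocytic genes Lrp2 and Dab2 were 3.77 and 3.37 times higher. The secreted antagonists Cer1 and Dkk1, known from anterior visceral endoderm, were 8.52 and 4.20 times higher, and Hhex, of the same region, was 3.07 times higher. Afp (alpha-fetoprotein) fell from 13.38 ± 0.11 to 10.70 ± 0.16 on the log2 scale (SD, n = 3), 6.45 times lower. Fgb, Apoa2, Rbp4, Fga, Apoa1 and Fgg were between 5.14 and 34.9 times lower, while the apolipoprotein genes Apob and Apoa4 were 2.14 and 2.55 times higher. The control means of Amn, Cer1 and Apoa4 and the RA means of Fgb, Fga and Fgg lay below the filter level.

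In full, 15 of 33 members rose and 12 fell, with the same counts when adjusted over the list alone, and their limma adjusted p ran from 5.99e-10 to 0.0376. The other rises were Rhox5 (log2 fold change 2.35 ± 0.11), Cited1 (1.31 ± 0.13), Spink1 (1.15 ± 0.08), Apob (1.10 ± 0.19), Apoa4 (1.35 ± 0.39), Sox7 (0.91 ± 0.22), and Foxa2 and Sox17 as above. The other falls were Gata6 (-1.53 ± 0.10), Ttr (-1.21 ± 0.08), Apoc2 (-1.10 ± 0.14), Hnf4a (-0.98 ± 0.14) and S100g (-0.37 ± 0.12). The median was 0.26 and the limma camera adjusted p was 0.511. The fry test, which looks at the list alone, gave a direction down (limma fry adjusted p = 0.0141), so the median and this test differ in sign. For Hnf4a the mean of its 4 probe sets gave 0.05. The call of Apoa4 was lost without control array 2 or 3 (1.09 and 1.22), that of Sox7 without RA array 3 (0.74), and that of S100g without any single array except RA array 1 (-0.39 to -0.29) and without scaling. Of 17 parietal endoderm genes 8 rose and 5 fell, and 9 and 5 did so when adjusted over the list alone (median 0.49, limma camera adjusted p = 0.511). The proteoglycan Srgn and the activin antagonist Fst (3.50 times) were higher, and vimentin (Vim, 3.20 times) and nidogen (Nid1, 2.10 times) were lower. Without scaling this list passed (limma camera adjusted p = 0.0113), but Nid1 did not and 2 members were lower.

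**Figure D2:**
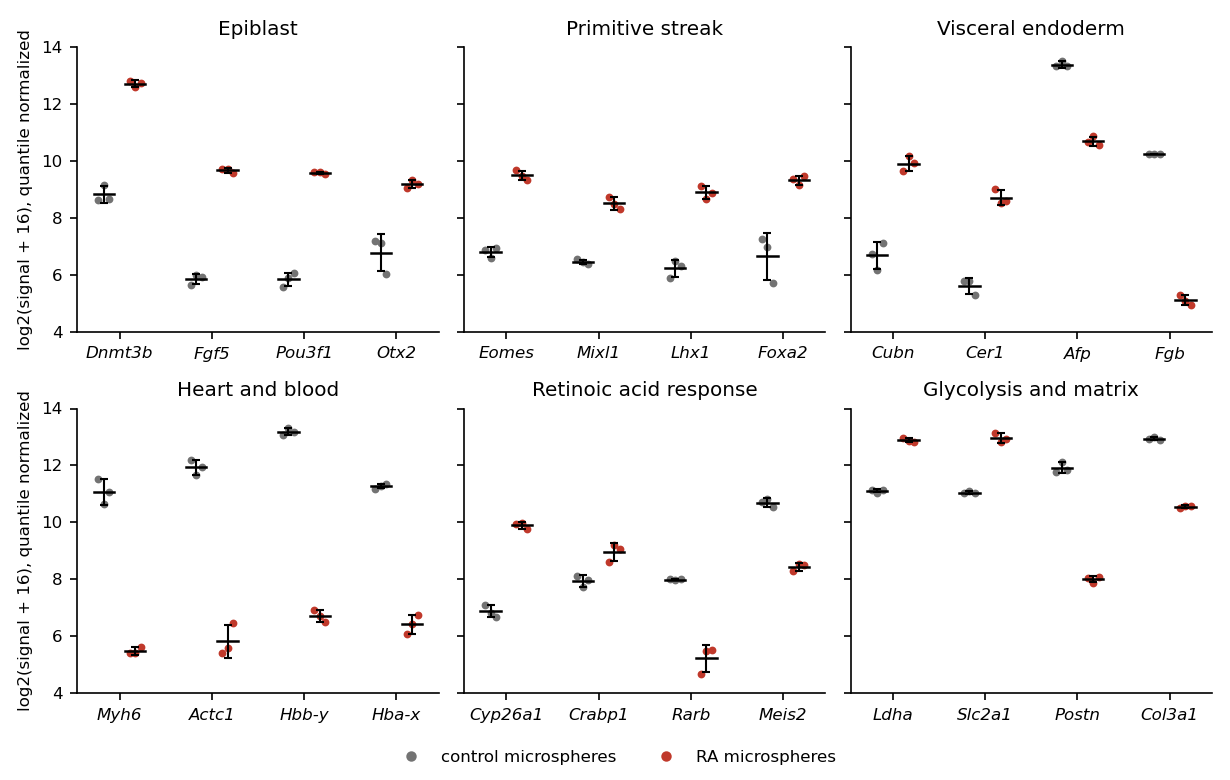
Quantile-normalized log2(signal + 16) on each array for 24 genes, grouped by list, with control arrays in grey and RA arrays in red. Points are arrays, and black lines are the mean ± SD (n = 3). Hbb-y lies at 13.19 in controls and 6.71 with RA, and in each gene shown the arrays of the groups do not overlap.

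Heart muscle genes had the lowest median of the 26 lists. Hand2, a transcription factor of the heart, was 8.12 times lower with RA, and Myl7, an atrial myosin light chain, was 33.2 times lower, beside Actc1 and Myh6. Of 26 measured members 0 rose and 17 fell, and 18 fell when adjusted over the list alone. The median was -1.75, with limma camera adjusted p = 4.85e-12 and adjusted p = 0.0505 with an estimated correlation. Among blood genes the embryonic globins Hbb-y, Hbb-bh1 (20.2 times) and Hba-x (29.0 times) were lower, while the transcription factor Myb was 2.20 times higher. Of 15 members 1 rose and 7 fell, and 1 and 8 did so when adjusted over the list alone. Their median was -0.65, with limma camera adjusted p = 0.000183 and adjusted p = 0.0904 with an estimated correlation. Endothelial genes were lower as well, with the tight junction gene Cldn5 10.2 times, Fli1 4.76 times and Ramp2 1.83 times lower, and Etv2 2.18 times higher. Of 16 endothelial members 1 rose and 10 fell, and 2 and 11 did so when adjusted over the list alone (median -0.96, limma camera adjusted p = 0.000121). Myl7, Hba-x and Ramp2 lie on chromosome 11, and without scaling Ramp2 did not pass and 2 endothelial members were higher. The RA means of Myh6, Cldn5 and Fli1 lay below the filter level. The call of Etv2 was lost without RA array 3 (0.94), and 4 blood genes were lower without control array 3.

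Mesenchymal and matrix genes were lower with RA. Periostin (Postn) was 15.0 times lower, smooth muscle actin (Acta2) 14.6 times and type III collagen (Col3a1) 5.22 times, while Thy1 was 6.43 times higher. Of 18 members 1 rose and 13 fell, and 2 and 13 did so when adjusted over the list alone (median -1.62, limma camera adjusted p = 9.69e-10). Among paraxial and lateral mesoderm genes, Foxf1, Tcf21 and Prrx1 were 4.22, 3.08 and 2.91 times lower, and Tbx1 was 3.60 times higher. Of 14 members 1 rose and 8 fell, and 1 and 9 did so when adjusted over the list alone (median -1.13, limma camera adjusted p = 0.000363). Epithelial genes went the other way, with Epcam 2.79 times and the splicing factor Esrp1 2.56 times higher beside Cdh1, and keratin 19 (Krt19, on chromosome 11) 2.14 times lower. Of 18 epithelial members 10 rose and 2 fell, with the same counts when adjusted over the list alone (median 0.70, limma camera adjusted p = 0.000363). The control means of Thy1 and Tbx1 lay below the filter level. Without scaling, and without RA array 1 and control array 3 together, 1 epithelial member was lower.

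The neural genes Fabp7 and Sox1 were among the 12 largest rises. Stmn2, a microtubule regulator of neurons, was 6.60 times higher with RA, and the adhesion gene Ncam1 was 3.15 times lower. Of 16 members 5 rose and 1 fell, also when adjusted over the list alone. The median was 0.47, with limma camera adjusted p = 0.00631 and adjusted p = 0.266 with an estimated correlation. In the neural crest list Snai2 and Ednrb were 8.70 and 2.66 times lower, and Foxd3 and Erbb3 (1.60 times) were higher. As above, the control means of Sox1 and Foxd3 lay below the filter level. Of 10 members 2 rose and 3 fell, and 3 and 3 did so when adjusted over the list alone (median -0.09, limma camera adjusted p = 0.737).

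Posterior Hox genes, which mark the trunk and tail, were lower with RA. Hoxa11, Hoxa10 and Hoxa9 were 4.80, 3.65 and 2.92 times lower, and Hoxb6 was 2.09 times higher. Of 15 members 1 rose and 9 fell, also when adjusted over the list alone. The median was -1.03, with limma camera adjusted p = 0.000397 and adjusted p = 0.0505 with an estimated correlation. Of 8 anterior Hox genes 1 rose (Hoxb3, 0.50 ± 0.17) and 1 fell (Hoxa3, -0.82 ± 0.22), and 0 and 1 did so when adjusted over the list alone. Hoxa4 and Hoxa5 had log2 fold changes of -0.97 ± 0.38 and 0.71 ± 0.39, and the list's median was -0.27 (limma camera adjusted p = 0.604). The call of Hoxb3 was lost without any single array except control array 2 (0.42 to 0.54), and that of Hoxb6 without any except control array 1 (0.71 to 1.17). That of Hoxa3 was lost without control array 1 (-0.77) or 2 (0.27). Its main probe set lay at 7.16, 7.11 and 7.01 on control arrays 1, 2 and 3, with an RA mean of 6.27. The value of 0.27 therefore goes with a switch to another probe set. Hoxa4 was at -1.22, past the threshold, without RA array 3 and at -0.52 without RA array 2. Hoxa5 was at 1.08 without control array 1 and at 0.26 without control array 2. The RA means of Hoxa4 and Hoxa11 and the control mean of Hoxb6 lay below the filter level. The 4 probe sets of Hoxa3 ranged from -1.07 to 0.59. Without scaling Hoxb3 and Hoxa3 did not pass, and Hoxb3 and Hoxb6 lie on chromosome 11.

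Of 8 trophoblast genes 4 rose and 0 fell, and 5 rose when adjusted over the list alone. Besides Eomes, which the epiblast-derived streak also expresses, these were the homeobox gene Rhox9 (2.78 times higher), Tpbpa (2.13 times) and Plac1 (1.53 times). The median was 0.58, with limma camera adjusted p = 0.00174 and adjusted p = 0.0505 with an estimated correlation. Tpbpa did not pass without control array 2 (0.84) or RA array 2 (0.87), nor Plac1 without any single array except control array 2 (0.42 to 0.68), and 2 trophoblast genes were higher without RA array 2. In the germ cell list the meiotic gene Sycp3 was 3.79 times higher and Stra8 lower, 1 of 8 members each way, and 2 rose and 1 fell when adjusted over the list alone. Prdm1 and Kit had log2 fold changes of 0.42 ± 0.15 and -0.19 ± 0.18, with Kit at -0.0115 without control array 1 and -0.38 without control array 3. The germ cell median and mean were -0.0034 and -0.02, while camera gave a direction up (limma adjusted p = 0.810).

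Genes of glycolysis and the hypoxia response rose almost throughout. Lactate dehydrogenase (Ldha) rose from 11.11 ± 0.05 to 12.89 ± 0.07 on the log2 scale (SD, n = 3), 3.44 times higher with RA. The glucose transporter Slc2a1 was 3.76 times higher, the kinase Pdk1, which limits pyruvate oxidation, 3.59 times, and Bnip3 3.29 times. Of 17 members 15 rose and 0 fell, also when adjusted over the list alone (median 1.19, limma camera adjusted p = 7.83e-12). Of 20 cell cycle genes 14 rose and 0 fell, also when adjusted over the list alone, with Mcm2, Ccna2, Mcm3 and Mcm5 between 1.46 and 1.93 times higher. Without RA array 1 the log2 fold change of Mcm2 was 0.59 in place of 0.95. Its main probe set lay at 10.72, 10.73 and 10.64 on RA arrays 1, 2 and 3. The move therefore goes with a switch to its other probe set and not with array 1 alone. Their median was 0.41, with limma camera adjusted p = 2.34e-06 and adjusted p = 0.0505 with an estimated correlation. Of 13 cholesterol synthesis genes 8 rose and 0 fell, and 9 rose when adjusted over the list alone (median 0.52, limma camera adjusted p = 8.68e-06). Sqle, Idi1, Cyp51 and Hmgcs1 were between 1.72 and 1.97 times higher.

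Targets of p53 were lower with RA. The death receptor gene Fas was 8.91 times lower, the cell cycle inhibitor Cdkn1a 3.13 times, Perp 2.79 times and Ccng1, on chromosome 11, 1.88 times. Of 11 members 0 rose and 6 fell, and 7 fell when adjusted over the list alone. The median was -0.53, with limma camera adjusted p = 0.00480 and adjusted p = 0.0617 with an estimated correlation. The RA mean of Fas lay below the filter level, so its fold is open to background. In the stress response list the immediate early genes Egr1 and Jun were 1.97 and 1.88 times lower, Ddit3 1.77 times lower and Asns 1.63 times higher. Of 16 members 1 rose and 5 fell, and 2 and 5 did so when adjusted over the list alone (median -0.20, limma camera adjusted p = 0.260). Of 17 Wnt, BMP and Nodal targets 6 rose and 1 fell, and 7 and 1 did so when adjusted over the list alone (median 0.16, limma camera adjusted p = 0.153). Besides Cer1 and Sp5, Id3 was 1.79 times higher and Bambi 2.40 times lower. Without scaling this last list passed (limma camera adjusted p = 0.0187), but Ccng1, Egr1, Jun and Ddit3 did not, 3 p53 targets were lower, and 0 stress response genes were lower and 2 higher. Without RA array 1 and control array 3 together, 3 stress response genes and 2 Wnt, BMP and Nodal targets were lower.

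Over the 26 lists 18 passed the limma camera threshold, 10 higher and 8 lower, and 9 did so with an estimated correlation. Those 9 lay close to the threshold there, with limma camera adjusted p from 0.0315 to 0.0470. Without RA array 1 and control array 3 together, 18 lists passed as well.

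Genes of chromosome 11 were lower with RA as a group. This comparison was chosen after the data were seen, and gene order follows the GRCm38.p6 table. The median log2 fold change of its 1119 tested genes lay at -0.23 relative to the other chromosomes (95% bootstrap interval -0.25 to -0.19). The bootstrap resampled genes and not arrays, so the interval does not measure the spread between samples. Per array, the median of its genes relative to the others was 0.12, 0.10 and 0.12 in controls and -0.14, -0.11 and -0.12 with RA. Of its genes 72 were higher and 320 lower, so that it held 8.24% of tested genes, 15.0% of lower calls and 3.69% of higher calls. The other chromosomes had medians between -0.02 and 0.08. In 20 bins of neighbouring genes along the chromosome the median was below that of the other chromosomes. Without its genes, all 26 lists stayed on their side of the threshold.

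**Figure D3:**
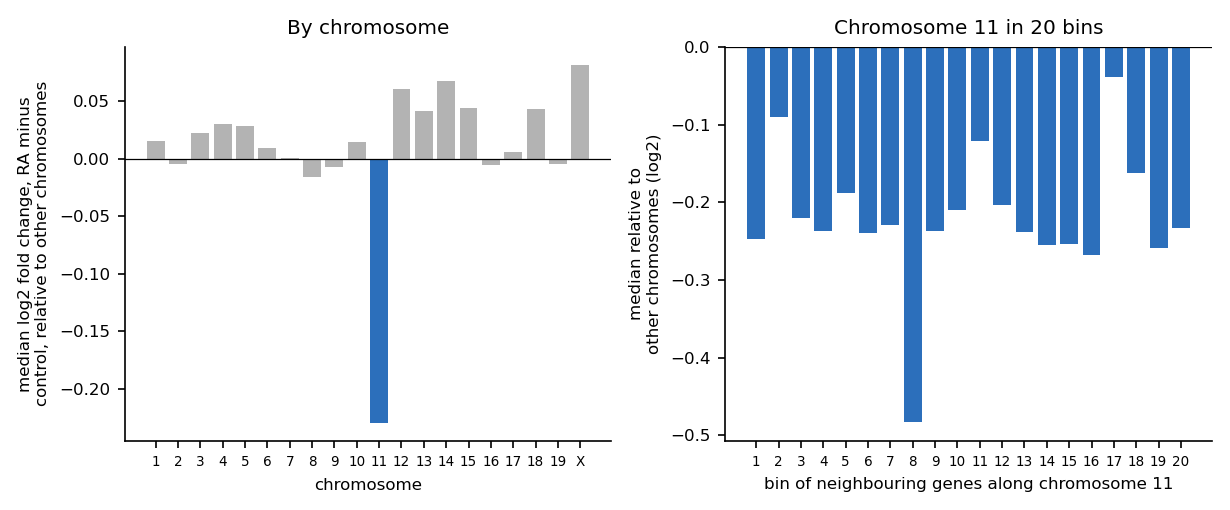
Median log2 fold change (RA minus control microspheres) of the genes of each chromosome relative to all other chromosomes, left, and of 20 bins of neighbouring genes along chromosome 11, right. Bars start at 0. Chromosome 11 lies at -0.23 and the other chromosomes between -0.02 and 0.08.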

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

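The tests of 5-prime signal on all RA arrays, of the visceral endoderm share, of visceral endoderm genes with at most 1 called probe set, and of clusters and signal level on chromosome 11 were chosen after the result was seen. The Gapdh 3-prime to 5-prime ratio was 34.0 on RA array 1, above the control arrays, which went up to 4.74. The actin ratio was 7.42, 4.35 and 4.90 on RA arrays 1, 2 and 3, all above the highest control array at 4.24. Among 3995 kept probe sets without a single gene name, 268 were higher and 215 lower with RA. Over all 27022 kept probe sets 3051 were higher and 3008 lower, a larger share.

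The first pattern is the number of changed genes, 4076. The low 5-prime signal of RA array 1 and the low overall signal of control array 3 are argued against as the whole cause, since 81.6% and 82.2% of these genes stayed past the threshold in the same direction without them. A lower 5-prime signal on all RA arrays stays open, because the actin ratio of 3 RA arrays lay above all controls, while the Gapdh ratio of RA arrays 2 and 3 did not. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05: only 1 split, the real one, gave as many genes, the highest other giving 0, and for lists 1 split gave 18 and the highest other 10. An effect of RA itself and any other difference in how the groups were cultured stay open as well and were not tested.

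The second pattern is the visceral endoderm list, which moved in both directions. A lower share of endoderm cells by itself would lower the genes together, so it does not account for the 15 members that rose. These rises are part of the pattern itself and are no separate test of it. Part of the falls may still come from a lower share. Foxa2 and Sox17, which rose, are also in the definitive endoderm list, so their rises need not come from visceral endoderm. Among the 8 members with several called probe sets, 4 higher and 4 lower, 0% had probe sets that went opposite ways, which argues against misread transcripts for these. The argument is weak, because opposite calls were rare in general, in 36 of 2102 changed genes with several kept probe sets. For the other 19 changed members, with at most 1 called probe set, that explanation stays open, as for Hnf4a, whose 4 probe sets ranged from -0.98 to 0.82. A change within the endoderm or a different mix of endoderm cell types was not tested.

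The third pattern is the lower level of chromosome 11 genes. Regulation of a few clusters is argued against, since 0 of 20 bins along the chromosome had a median at or above that of the other chromosomes. Signal level and gene density are argued against, since 0 of 10000 random lists matched on them were as low, the lowest at -0.04. A difference in copies of chromosome 11 and an effect of RA on the chromosome as a whole cannot be told apart, since the arrays do not measure DNA. Its genes not called changed lay at -0.10 (95% bootstrap interval over genes -0.13 to -0.08). This favours neither, because leaving out the called genes shrinks the shift by construction.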

How the results depend on the processing

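Scaling to a common trimmed mean, leaving out 2 arrays in doubt and leaving out chromosome 11 were chosen after seeing the data. Without scaling, 2401 genes changed and 651 were lower. Over all kept probe sets 3051 were higher. With a 2-fold minimum 1085 changed, 414 higher and 671 lower. With an estimated correlation 9 lists passed and the retinoic acid response list had an adjusted p of 0.0703. With fry, visceral endoderm had an adjusted p of 0.0141 in the opposite direction. For these the cause was not tested, except the fold minimum, which is stricter by construction. Of the lists lost with an estimated correlation, retinoic acid response, trophoblast and p53 had estimates of -0.0073, -0.0268 and -0.0414. These lie below the preset 0.01, so a higher correlation does not account for their loss. The other lists lost had estimates from 0.0164 to 0.194. Fry also gained neural crest, germ cells, stress response and Wnt, BMP and Nodal targets, and no scaling the last of these and parietal endoderm. Other alternatives kept the gene counts within 1.5 times and the same 18 lists. The call was lost and the estimate changed sign, with no call in the other direction, for Hnf4a as the mean of its probe sets (0.047). The same held for Hoxa3 without control replicate 2 (0.27, range with an array left out -0.94 to 0.27). It also held for Dnmt3a without control replicate 3 (0.21, range -1.26 to 0.21). For Hoxa3 and Dnmt3a another probe set was then taken, and in each gene the probe sets differ. Of 2204 values of named genes under other alternatives 2131 kept direction and call, 69 lost the call, 3 gained it and 1 lost it with a change of sign. With an array left out these were 843, 41, 1 and 2 of 887. Leaving out each array gave 3265 to 3627 changed genes and 18 lists, and 76.7% to 82.2% of the changed genes stayed. No pairing of arrays by replicate number was seen. Deviations of equal numbers correlated at -0.09, -0.01 and -0.03, and 0 arrays correlated best with their own number. With 3 arrays in each group this cannot exclude that equal numbers were handled together. The fit with a replicate block gave 3724 changed genes, 1775 higher and 1949 lower, and 18 lists, with Hoxb3 and Nodal not past the threshold. Signal over background limits dim genes.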

Other observations

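The 13 lists and the genes below were chosen after the main results were seen, from which some members had been noticed, so their tests are not independent evidence. With an estimated correlation 5 of these lists passed, with limma camera adjusted p from 0.0181 to 0.046. Liver-type serum proteins were far lower with RA: 18 of 20 measured members fell and 0 rose (median log2 fold change -3.12, limma camera adjusted p = 4.33e-16), 19 adjusted over the list alone. Fabp1, the fatty acid binding protein of liver and gut, was 15.7 times lower and hemopexin (Hpx) 12.2 times lower. Platelet genes fell in 7 of 10 members (median -1.35, limma camera adjusted p = 1.02e-05), among them Plek, 14.6 times lower. Of 14 macrophage genes 6 fell (median -0.75, limma camera adjusted p = 0.00364, adjusted p = 0.142 with an estimated correlation), with C1qb 5.45 times and Tyrobp 4.82 times lower. Smooth muscle genes fell in 6 of 9 (median -0.75, limma camera adjusted p = 0.000444). Of 10 mesothelium and epicardium genes 2 rose and 6 fell (median -1.14, limma camera adjusted p = 0.0272, adjusted p = 0.109 with an estimated correlation), with Bnc1 12.4 times lower. The RA means of Hpx, Plek, C1qb and Bnc1 lay below the filter level of 5.74, so these folds are open to background.

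Imprinted genes were mostly lower, with 16 of 24 members down and 3 up (median -0.57, limma camera adjusted p = 5.14e-06). Dlk1 was 9.65 times lower, Plagl1 4.90 times and Igf2 3.22 times, while Phlda2 was 3.05 times higher. All 3 measured genes of the Rhox homeobox cluster were higher, with Rhox6 5.72 times and Rhox5 5.10 times. Ribosome biogenesis genes rose in 17 of 22 members and fell in 0 (median 0.60, limma camera adjusted p = 3.75e-10), with Dkc1, a pseudouridine synthase, 2.56 times higher. Of 36 oxidative phosphorylation genes 1 rose and 21 fell (median -0.30, limma camera adjusted p = 6.56e-07, adjusted p = 0.0692 with an estimated correlation). Of 13 neural tube patterning genes 7 rose and 0 fell (median 0.93, limma camera adjusted p = 5.99e-05, adjusted p = 0.0569 with an estimated correlation), with Rfx4 5.51 times and Hesx1 4.21 times higher, from control means below the filter level. The lists for DNA methylation (3 up and 2 down of 10, adjusted p = 0.830), lysosome (5 and 5 of 21, adjusted p = 0.970) and interferon response (1 and 3 of 11, adjusted p = 0.830) did not pass limma's camera test, although the cathepsin Ctsc was 7.81 times higher.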
